A study of Mus musculus with 6 samples.

How the data were processed

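The samples were Kupffer cells, the resident macrophages of the liver, from mice carrying a floxed Myd88 allele and the Vil1Cre transgene, a Cre recombinase driver of the intestinal epithelium. The labels put 3 libraries in an untreated group and 3 in a group treated with 5-HT (serotonin). Library names begin with KO in the untreated group and with 5-HT in the treated group. These names alone do not tell whether the groups differ in more than the treatment. Dose, route and duration of the treatment, whether the mice or the isolated cells were treated, the way the cells were isolated, and the number of animals behind each library are not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical in part. Per the labels' protocols, total RNA was extracted with TRIzol, and mRNA libraries were sequenced on a NovaSeq system.

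The deposited table gives 2 kinds of value for each of 56691 genes in the 6 libraries. The first is a raw read count per gene, per the file headers, and the submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.1 and the mm10 build without saying which step used which. The second is the FPKM (fragments per kilobase of exon, scaled to library size) that the authors deposited beside each count. Each deposited FPKM of at least 1 was checked against the value computed from the count, the exonic length and the column's total: 100% of them lay within 0.5% or the rounding of the second decimal. FPKM was therefore scaled by the counts assigned to genes. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes may be shared. Genes of multigene families, among them immunoglobulin segments, Saa1 and Saa2, and the cathepsin gene Ctsj, are reported as uncertain because reads can be split between copies.

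Total counts per library ran from 15390956 to 19050039. Identifiers were matched to GENCODE M21 (GRCm38): 52073 of 56691 (91.9%) were found there. Only 1472 of the matched genes had the same start and end in the deposited table, although the notes name mm10, so all positions printed are those of GENCODE M21 on GRCm38, taken by identifier. Symbols are those of the deposited table; a symbol shared by several rows was replaced by the identifier, except for members of the fixed lists.

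The main comparison was 5-HT treated against untreated in R 4.3.3. Counts were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood fit and test, two-sided), with Benjamini-Hochberg adjustment over the 16641 genes tested and a threshold of 0.05. The plan named limma on log2(FPKM + 1) as the main test unless whole-number counts were deposited; they were, so edgeR became the main test as the plan provided. Standard errors of log2 fold changes were computed as the fold change divided by the square root of the F statistic. Means and SDs are of FPKM over 3 libraries. Before the data were examined, 30 program lists and 15 cell type marker lists were fixed. They were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01), which asks whether a list's genes move relative to all other genes, with adjustment over the 45 lists. The result of 1 list past the threshold is not reported here, although the counts of lists include it. Each list was tested again with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. Terms from the GO and pathway columns of the deposited table, with 10 to 300 tested genes each, were tested with camera in 1 family of 3610. A result is given as adjusted over the list alone where only the list's own genes were adjusted for.

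The rule for named genes was also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, with a mean FPKM of at least 5 in the higher group and a symbol that is not a clone name. It adds up to 4 genes of smallest p from each list past the threshold, from the uptake lists, the serotonin list and the Kupffer cell list; Myd88; each serotonin receptor with a mean FPKM of at least 0.5; and the 2 most abundant members of each cell type list. Genes named outside it are said to be chosen after their values were seen.

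On simulated counts drawn for the 16641 genes from their means, dispersions and library sizes, with 200 genes changed, edgeR recovered 2 of 67 genes changed 1.5-fold, 25 of 67 changed 2-fold and 51 of 66 changed 4-fold, and 5 of its 83 calls (6.02%) were false. DESeq2 1.42.0 made 143 calls on the same counts, of which 33 (23.1%) were false. The simulated genes varied independently, so the simulation does not test lists of genes that vary together. Alternatives covered the filter on low values, the scaling, DESeq2, limma on FPKM with pseudocounts of 0.1, 1 and 5, array weights, a replicate block, and leaving out each library in turn. The terms were also tested without immunoglobulin segments, an alternative chosen after seeing the data.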

Results

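Gene expression was measured by mRNA sequencing in Kupffer cells of Vil1Cre-Myd88fl/fl mice, with 3 untreated and 3 5-HT treated libraries. The series concerns serotonin production driven by commensal bacteria and the delivery of synthetic and viral vectors in vivo, and the comparison asks what 5-HT changes in the liver's resident macrophages. Untreated replicates 1 to 3 held 18187617, 18235766 and 19050039 counts, and 5-HT treated replicates 1 to 3 held 15982366, 15390956 and 17093251. All 6 libraries were kept as separate samples, as labelled. The closest pair, untreated replicates 1 and 3, differed by 6.98 times counting noise (chi-square per degree of freedom over 16676 genes), against 25.5 and 29.98 for the pairs with untreated replicate 2. Preparations of 1 sample can also differ by more than counting noise, so these values do not show that the replicates are separate animals. The groups separated along the first principal component, which held 41.6% of the variance. The second component (23.03%) set 5-HT treated replicate 2 apart from the other treated libraries.

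**Figure D1:**
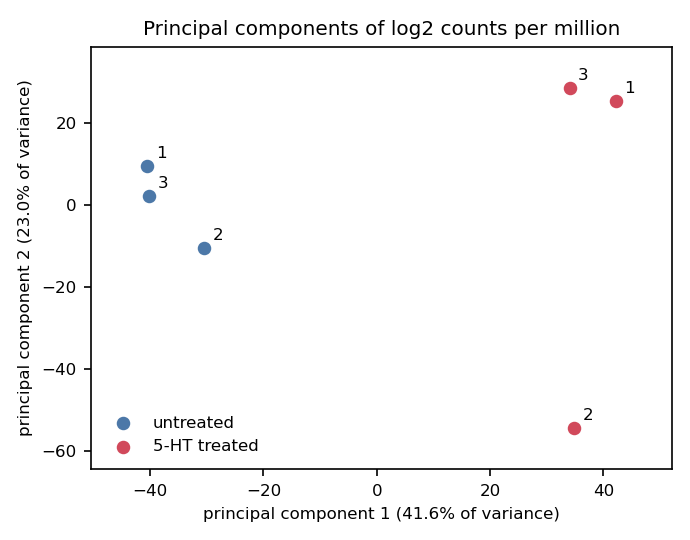
Principal components of log2 counts scaled to library size of the 6 libraries, with the first component (41.6% of variance) on the x axis and the second (23.03%) on the y axis; numbers are replicates and colours are groups. The treated libraries lie right of the untreated ones, and 5-HT treated replicate 2 lies at -54.4 on the second component.

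Myd88, the adaptor of most Toll-like receptors and the floxed gene of this strain, was expressed in every library. The driver deletes it in intestinal epithelium, so its level in Kupffer cells is no check of the genotype. Its FPKM was 19.5, 14.4 and 20.2 in untreated replicates 1 to 3 and 29.2, 30.1 and 28.8 in 5-HT treated replicates 1 to 3, a rise of 1.63-fold (log2 0.71, SE 0.14, edgeR adjusted p = 0.0286). The gene (ENSMUSG00000032508) lies on chromosome 9 from 119335934 to 119341411, minus strand, in GRCm38. The call was lost in 5 of the 6 fits that left out 1 library, where the adjusted p reached 0.0898; the exception was the fit without untreated replicate 2.

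With 5-HT, 757 genes were higher and 531 lower at an edgeR adjusted p under 0.05. Of these, 299 rose and 199 fell by at least 2-fold. The rises ranked here are of called genes with a mean of at least 5 FPKM in the higher group and no clone name. The largest was that of Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11 from 78920787 to 78960254, plus strand), from 0.16 ± 0.061 to 21.9 ± 9.67 FPKM (SD, n = 3 each). This was 134-fold (log2 7.07, SE 0.47, edgeR adjusted p = 0.00107). Npy, the gene of neuropeptide Y on chromosome 6 from 49822710 to 49829507, went from 0.193 ± 0.17 to 5.66 ± 0.406 FPKM (log2 4.81, SE 0.48, edgeR adjusted p = 0.00245). The other 8 of the 10 largest rises among genes with a mean of at least 5 FPKM in the higher group belong to multigene families and are uncertain as single genes: the acute-phase gene Saa2 (log2 5.66), the cathepsin gene Ctsj (log2 5.29), and the immunoglobulin genes Ighv9-2, Ighg3, Ighv6-3, Igkv1-122, Ighv1-9 and Igkv8-28 (log2 6.82, 5.68, 5.48, 5.05, 4.50 and 4.47). Saa2 lost its call in 6 of 21 alternative fits and Ighv9-2 in 4 of 21, while Ighv1-9, Igkv8-28 and Igkv1-122 lost theirs in 9, 4 and 3 of 23.

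Among called genes with a mean of at least 5 FPKM in the higher group and a symbol that is not a clone name, the largest fall was that of Rgs16, a regulator of G-protein signalling (chromosome 1 from 153740349 to 153745468, plus strand), from 9.90 ± 4.89 to 1.69 ± 0.344 FPKM (log2 -2.55, SE 0.43, edgeR adjusted p = 0.0151). Its call was lost in 5 of 23 alternative fits, among them those without untreated replicate 1 or 3 or without 5-HT treated replicate 1, with adjusted p up to 0.0845. Eln, the elastin gene (chromosome 5 from 134702593 to 134747323, minus strand), went from 5.59 ± 0.536 to 1.05 ± 0.244 FPKM (log2 -2.40, SE 0.19, edgeR adjusted p = 0.00157), and Col15a1, a collagen gene, had a log2 change of -2.22, a call lost in 3 of 21 alternative fits. All 11 stellate cell and fibroblast markers had negative log2 values in the same comparison (median -1.01, camera adjusted p = 0.000261). The list did not pass with an estimated correlation (adjusted p = 0.363) or at a mean FPKM of at least 5 (adjusted p = 0.0557). Ddit4, a stress-induced inhibitor of mTORC1, fell from 78.05 ± 6.87 to 18.4 ± 4.92 FPKM (log2 -2.08, SE 0.19, edgeR adjusted p = 0.00165). The cell cycle inhibitor gene Cdkn1c fell from 19.1 ± 4.33 to 4.78 ± 0.905 FPKM (log2 -1.99) and Bdh1, a ketone body enzyme, from 6.47 ± 2.24 to 1.33 ± 0.324 FPKM (log2 -2.28). Hsd3b5, Vstm4, Sntb1 and Rnase10 completed the 10, with log2 changes of -2.52, -2.12, -2.00 and -1.94; Hsd3b5 and Rnase10 lost their calls in 14 and 5 of 21 alternative fits.

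All 1288 called genes had groups that did not overlap, as did 4948 of the 16641 tested genes (29.7%, against the 10% that chance gives for 3 against 3). The counts depended on single libraries: they were 218 higher and 111 lower without untreated replicate 1, 220 and 116 without untreated replicate 3, and 338 and 222 without 5-HT treated replicate 1. DESeq2 called 1241 higher and 1018 lower.

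**Figure D2:**
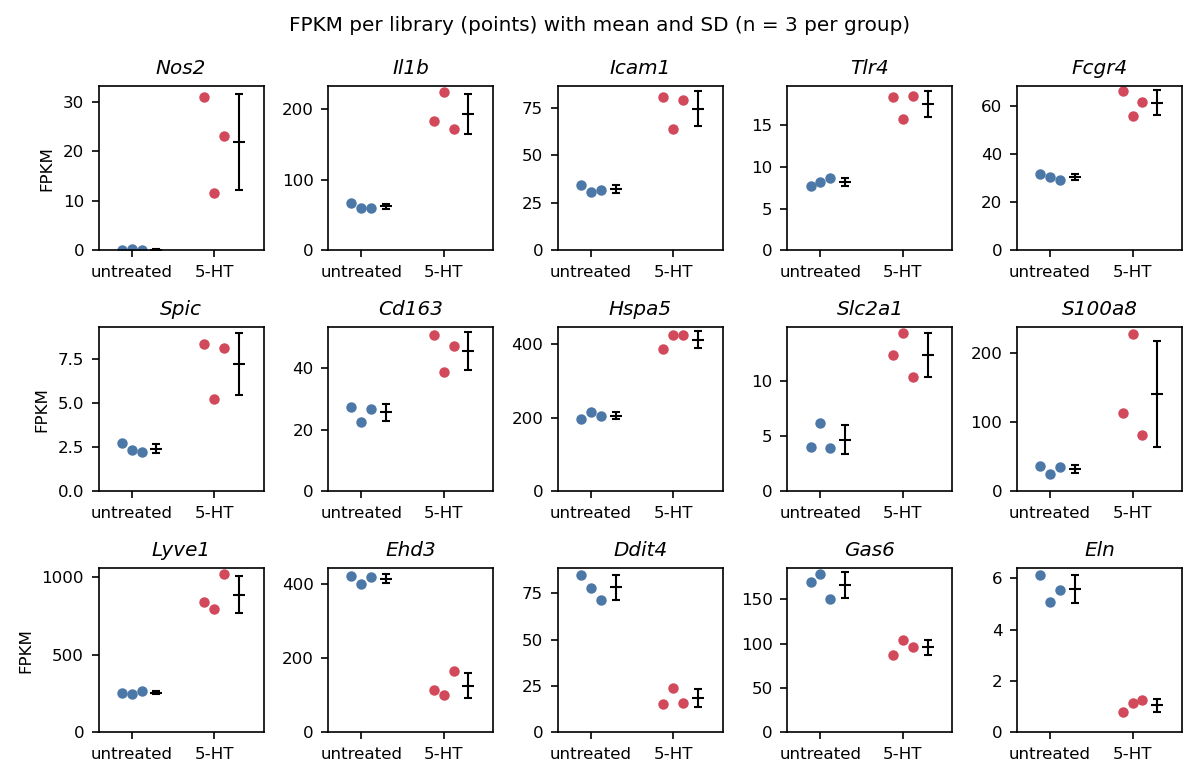
FPKM of 15 genes in each library (points; untreated in blue, 5-HT treated in red), with the mean and SD of each group (n = 3) beside the points; each y axis starts at 0. In each gene drawn, the 3 libraries of one group lie above the 3 of the other.

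Of the 45 gene lists, 10 were higher and 3 lower by camera with a preset correlation. No list kept its call with an estimated correlation, where the lowest adjusted p was 0.312. With fry, 8 of the 13 kept it; the Kupffer cell, NF-kB, neutrophil, oxidative phosphorylation and ribosomal protein lists did not (fry adjusted p = 0.0648, 0.0648, 0.128, 0.255 and 0.403). Other ways of dividing the same 6 libraries into groups of 3 called between 12 and 19 lists, so the number of lists called does not set this comparison apart. By edgeR they called 0 genes (210 to 1430 at an unadjusted p under 0.05), by limma 0 and by DESeq2 0 to 181. Each such division mixes libraries of both groups, so the treatment difference widens the spread within its groups. With 10 divisions in all, the gene counts cannot set the comparison apart either.

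Part of the NF-kB inflammatory genes rose. Of 27 tested NF-kB inflammatory genes, 7 rose, none fell and 20 did not pass by edgeR, and 9 rose when adjusted over the list alone (camera adjusted p = 2.16e-06; adjusted p = 0.426 with an estimated correlation). Besides Nos2, the cytokine gene Il1b went from 62.1 ± 4.09 to 193 ± 27.8 FPKM (log2 1.64, SE 0.13, edgeR adjusted p = 0.00138). Icam1, an adhesion receptor for leukocytes, rose 2.32-fold (log2 1.21, edgeR adjusted p = 0.00235), and Tnfaip2 rose with a log2 change of 1.54. Tnf and Il6, chosen after their values were seen, did not pass (log2 0.53 and -1.04, edgeR adjusted p = 0.0929 and 0.14). Of 23 Toll-like receptor and adaptor genes, 7 rose and none fell, and 11 rose when adjusted over the list alone (camera adjusted p = 2.16e-06; adjusted p = 0.363 with an estimated correlation). Tlr4, the endotoxin receptor gene (chromosome 4 from 66827584 to 66930284, plus strand), went from 8.24 ± 0.47 to 17.6 ± 1.6 FPKM (log2 1.10, SE 0.10, edgeR adjusted p = 0.00187). Tlr2, Rela and Tirap rose with log2 changes of 0.80, 0.61 and 0.85. The type I interferon list went the other way without passing: 1 of its 29 genes rose (Gbp2, log2 1.24) and 2 fell (Ifi44 and Ifit3b, log2 -1.42 and -0.87, all 3 chosen after their values were seen), and 1 rose and 3 fell when adjusted over the list alone, with a median log2 change of -0.40 (camera adjusted p = 0.0561; adjusted p = 0.924 with an estimated correlation). It passed as lower in 6 of 25 alternative settings, among them the fits without untreated replicate 1, without untreated replicate 3 and without 5-HT treated replicate 3 (adjusted p = 0.00288, 0.00301 and 0.000124).

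Neutrophil markers rose in the same libraries. Of 10 tested, 6 rose, none fell and 4 did not pass, and 8 rose when adjusted over the list alone (camera adjusted p = 1.06e-06; adjusted p = 0.445 with an estimated correlation). S100a8 went from 32.6 ± 5.97 to 141 ± 76.5 FPKM and S100a9 from 79.9 ± 22.6 to 301 ± 146 FPKM (log2 2.11 and 1.91, edgeR adjusted p = 0.0168 and 0.0235). Without untreated replicate 1 and without untreated replicate 3 both lost the call, with adjusted p up to 0.0816 and 0.0914, as S100a9 did without 5-HT treated replicate 1 and with the replicate block. Mmp8, Cxcr2 and Csf3r had log2 changes of 3.04, 2.72 and 1.43 and lost the call without either of the same untreated replicates. Their spread was wide because 5-HT treated replicate 2 had the highest values, with S100a8 at 227 FPKM against 113 and 81.9 in 5-HT treated replicates 1 and 3.

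Part of the genes of Kupffer cell identity rose. Of 17 tested, 6 rose, none fell and 11 did not pass, and 13 rose when adjusted over the list alone (camera adjusted p = 1.57e-07; adjusted p = 0.445 with an estimated correlation). Spic, a transcription factor of iron-recycling macrophages (chromosome 10 from 88674772 to 88685015, minus strand), went from 2.44 ± 0.276 to 7.25 ± 1.75 FPKM (log2 1.58, SE 0.21, edgeR adjusted p = 0.00606). The complement component gene C6 rose from 19.9 ± 4.34 to 42.5 ± 3.53 FPKM (log2 1.10), Cd163, the haemoglobin scavenger receptor gene, from 25.7 ± 2.66 to 45.7 ± 6.22 FPKM (log2 0.84), and Adgre1, which encodes the macrophage marker F4/80, with a log2 change of 0.70. Adgre1 lost its call in 4 of 23 alternative fits (adjusted p up to 0.0953), Cd163 in 2 and C6 in 1. In the same libraries the stellate cell and endothelial lists had median log2 values of -1.01 and -0.36. Iron and heme genes, which share 3 members with the Kupffer cell list, followed: 4 of 12 rose and none fell, and 6 rose when adjusted over the list alone (camera adjusted p = 0.00181; adjusted p = 0.363 with an estimated correlation). Hmox1, the heme oxygenase gene, rose 1.70-fold (log2 0.76, edgeR adjusted p = 0.0118), and the metal transporter gene Slc11a1 had a log2 change of 0.66. Their calls were lost in 2 and 10 of 23 alternative fits.

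Part of the list of receptors for antibody and complement rose, a list that also holds the complement component genes C1qa, C1qb and C1qc. Of 16 tested, 7 rose, 1 fell and 8 did not pass, and 13 rose and 3 fell when adjusted over the list alone (camera adjusted p = 4.45e-06; adjusted p = 0.312 with an estimated correlation). Fcgr4, an activating receptor for IgG (chromosome 1 from 171018920 to 171029761, plus strand), went from 30.5 ± 1.24 to 61.3 ± 5.11 FPKM (log2 1.02, SE 0.09, edgeR adjusted p = 0.00169). Fcgr3, another activating receptor, and the anaphylatoxin receptor genes C3ar1 and C5ar1 rose with log2 changes of 0.80, 1.22 and 0.97. C3ar1 lost its call in 1 and C5ar1 in 4 of 23 alternative fits. The Kupffer cell list, which shares Vsig4 with this list, was higher in the same libraries (median log2 0.63, against 0.49 for this list). Neutrophil markers were higher there too (median log2 1.74). In 5-HT treated replicates 1 to 3, C5ar1 had 20.01, 23.03 and 15.1 FPKM and C3ar1 12.75, 12.8 and 8.66 FPKM. Fcgr3 had 92.56, 92.74 and 74.14 FPKM in them. Fcgr4, with 66.16, 55.97 and 61.81 FPKM, was lowest in replicate 2, where S100a8 was highest. Itgam, chosen after its values were seen and not past the threshold, had 15.8, 22.1 and 8.72 FPKM there. The gene that fell was Fcgr2b, the inhibitory IgG receptor, chosen after its values were seen, from 519 ± 18.5 to 351 ± 43.0 FPKM (log2 -0.56, edgeR adjusted p = 0.041). Endothelial markers had a median log2 value of -0.36 in the same libraries, without passing as a list. Which cells gave the reads of these receptors was not tested.

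The other uptake lists did not pass as lists in the edgeR fit. Among 22 scavenger and particle-uptake receptors, 4 rose and none fell, and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.305). These 4 were Olr1 (log2 2.01), Cd163, the C-type lectin receptor gene Clec4n (log2 0.79) and Marco, a receptor for bacteria and particles (34.9 ± 12.8 to 76.9 ± 8.42 FPKM, log2 1.14, edgeR adjusted p = 0.0489). Cd163 and Marco are also members of the Kupffer cell list. Marco's call was lost in 15 of 23 alternative fits, where its adjusted p reached 0.134. The call of Clec4n was lost in 8 of 23 and that of Olr1 in 3 of 21. Of 16 genes for the uptake of apoptotic cells, 1 fell and none rose, over all genes and adjusted over the list alone (camera adjusted p = 0.696). It was Gas6, the bridging ligand of the TAM receptors, which went from 166 ± 14.5 to 96.2 ± 8.36 FPKM (log2 -0.78, SE 0.11, edgeR adjusted p = 0.00777), a call lost in 1 of 23 alternative fits. Stab2, Timd4 and Cd300a had log2 values of -0.52, 0.75 and 0.40, none past the threshold. Of 26 clathrin endocytosis genes, 3 rose (Bin1, Epn2 and Dab2, log2 0.66, 0.70 and 0.63) and 1 fell (Hip1, log2 -0.58), the calls of Dab2, Hip1 and Epn2 being lost in 10, 8 and 7 of 23 alternative fits, and 4 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.29). None of 9 caveola and flotillin genes passed over all genes, and 3 fell when adjusted over the list alone (camera adjusted p = 0.102). Cav1, Cavin2, Cav2 and Ehd2 had log2 values of -0.62, -0.61, -0.46 and -0.61. The endothelial list had a median log2 value of -0.36 in the same libraries, without passing. Whether the reads of the caveola genes and Stab2 came from Kupffer or endothelial cells was not tested. Of 27 lysosome genes, 4 rose (Ctsb, Ctsd, Ctss and Hexa, log2 0.62, 0.41, 0.54 and 0.49, chosen after their values were seen) and none fell, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0839). The lysosome list passed as higher in 10 of 25 alternative settings, with adjusted p down to 0.00085 (limma without a filter), among them DESeq2 (0.0167), limma on log2(FPKM + 1) (0.0286) and the fit without untreated replicate 2 (0.0417). The caveola list passed as lower in 3 of 25, among them the fit without 5-HT treated replicate 2 (0.0247).

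Serotonin receptors were near the floor of detection. Of the receptor genes in the table, Htr7 alone had counts high enough to be tested, at 0.267 ± 0.0503 FPKM in untreated and 0.72 ± 0.202 FPKM in treated libraries (log2 1.45, SE 0.34, edgeR adjusted p = 0.0434). Its mean over the 6 libraries was 0.493 FPKM, and its call was lost in 7 of 12 alternative fits, among them the replicate block. Without 1 library in turn its adjusted p ran from 0.0454 to 0.161. Ddc, which encodes the decarboxylase that makes serotonin, went from 1.27 ± 0.399 to 0.377 ± 0.166 FPKM (log2 -1.75, edgeR adjusted p = 0.0372), a call lost in 14 of 21 alternative fits. Tgm2 and Maob had log2 values of 0.34 and -1.03 and did not pass. As a list of 7 tested genes, 1 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.942).

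Part of the genes of glycolysis and protein folding rose. Of 16 glycolysis genes, 6 rose, none fell and 10 did not pass, and 8 rose when adjusted over the list alone (camera adjusted p = 1.27e-06; adjusted p = 0.312 with an estimated correlation). The lactate exporter gene Slc16a3 went from 1.74 ± 0.352 to 5.64 ± 1.1 FPKM and the glucose transporter gene Slc2a1 from 4.72 ± 1.31 to 12.4 ± 1.98 FPKM (log2 1.70 and 1.40, edgeR adjusted p = 0.00376 and 0.00838); Hk2 and Aldoa had log2 changes of 0.77 and 0.63. The calls of Slc2a1, Hk2 and Aldoa were lost in 2, 5 and 3 of 23 alternative fits. Of 18 genes of the unfolded protein and integrated stress responses, 8 rose and 1 fell, and 9 rose and 3 fell when adjusted over the list alone (camera adjusted p = 8e-06; adjusted p = 0.379 with an estimated correlation). Those named by the rule were chaperones and folding enzymes of the endoplasmic reticulum: Hspa5 went from 206 ± 9.94 to 411 ± 22.6 FPKM (log2 1.01, SE 0.10, edgeR adjusted p = 0.00245), and Hsp90b1, Pdia6 and Calr had log2 changes of 1.05, 1.01 and 0.96. Herpud1, which acts in the degradation of misfolded proteins and was chosen after its values were seen, fell from 122 ± 8.86 to 58.5 ± 7.22 FPKM (log2 -1.05). In the same libraries neutrophil markers had a median log2 value of 1.74, and 30 of 147 immunoglobulin segments rose and none fell. Which cells the changes in both lists came from was not tested.

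Of 11 LXR targets, which serve cholesterol efflux and lipid handling, 2 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.379 with an estimated correlation). The cholesterol exporter gene Abca1 went from 26.3 ± 4.35 to 63.3 ± 10.1 FPKM (log2 1.27, edgeR adjusted p = 0.00674), Abcg1 had a log2 change of 0.70, and Mylip, which encodes a ligase that degrades the LDL receptor, fell by 0.83 on the log2 scale. The call of Mylip was lost in 4 of 23 alternative fits. Scd2 did not pass (log2 0.39). The list lost its call in 6 of 25 alternative settings: with the estimated correlation, with a mean FPKM of at least 5 by edgeR and by limma (adjusted p = 0.0623 and 0.0528), with quantile normalization (0.0784), with array weights (0.101) and without untreated replicate 2 (0.0552). None of 30 nuclear-encoded oxidative phosphorylation genes passed by edgeR, over all genes or adjusted over the list alone, and 29 of them had a negative log2 value, with a median of -0.21 (camera adjusted p = 0.00608; adjusted p = 0.894 with an estimated correlation). None of 38 ribosomal protein genes passed either, with a median of -0.15 (camera adjusted p = 0.0445; adjusted p = 0.924 with an estimated correlation), and that call was lost in 4 of the 6 fits without 1 library, without untreated replicate 1 or 3 or without 5-HT treated replicate 1 or 3, where the adjusted p reached 0.258, and with the replicate block (0.0815).

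**Figure D3:**
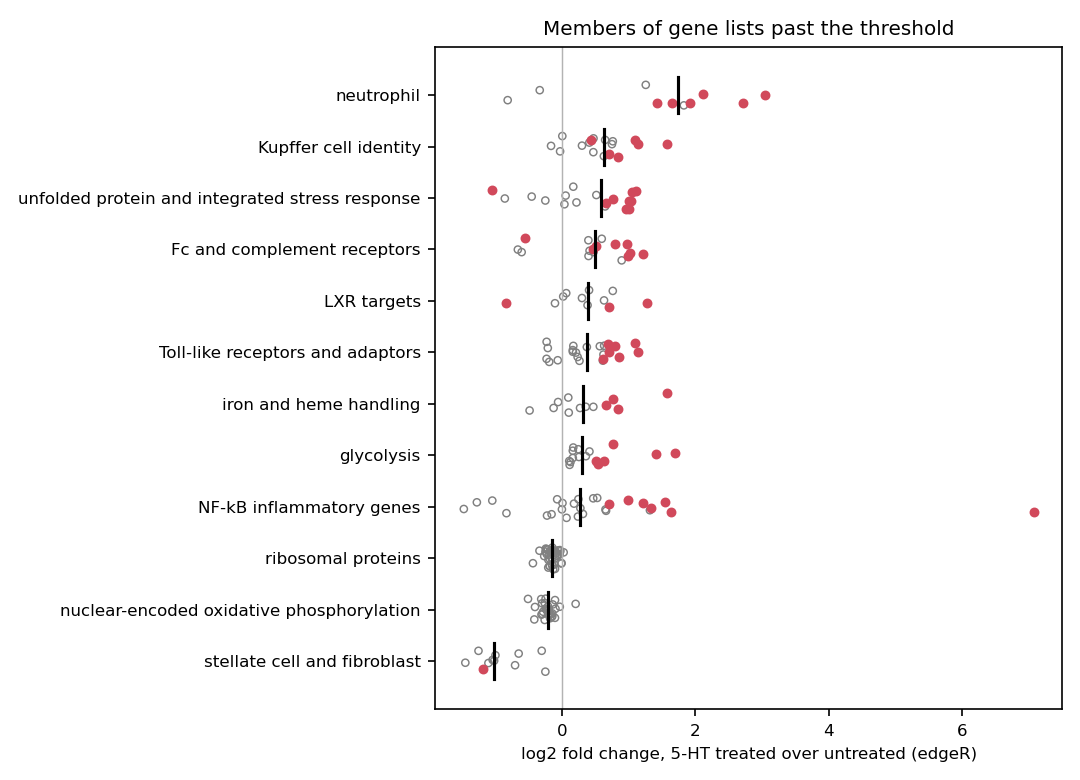
log2 fold change of each tested member (points) of the gene lists past the camera threshold, except 1 list not reported, 5-HT treated over untreated; filled points passed the edgeR threshold and bars are list medians. The medians run from 1.74 for neutrophil markers to -1.01 for stellate cell and fibroblast markers.

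Markers of other liver cells were abundant in the preparations. Clec4g, a gene of liver sinusoidal endothelium, had 691 ± 27.9 FPKM in untreated and 536 ± 110 FPKM in treated libraries, above the Kupffer cell gene Clec4f at 182 ± 33.5 and 284 ± 31.3 FPKM. Of 13 endothelial markers, 1 rose and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0733). The list passed as lower in 9 of 25 alternative settings, with adjusted p down to 0.000783 (without 5-HT treated replicate 3). The one that rose was Lyve1, the hyaluronan receptor gene (chromosome 7 from 110850607 to 110863239, minus strand), from 257 ± 10.2 to 887 ± 120 FPKM (log2 1.79, SE 0.13, edgeR adjusted p = 0.00138). Those that fell, chosen after their values were seen, were Ehd3, from 416 ± 12.1 to 127 ± 34.5 FPKM (log2 -1.71), and Kdr, Ptprb, Oit3 and Tek (log2 -0.78, -0.82, -0.74 and -0.76). All 11 stellate cell and fibroblast markers had negative log2 values, with a median of -1.01, and 1 of them, Reln, fell by edgeR, over all genes and adjusted over the list alone (log2 -1.18, edgeR adjusted p = 0.0124; camera adjusted p = 0.000261; adjusted p = 0.363 with an estimated correlation). The call of Reln was lost in 9 of 21 alternative fits, where its adjusted p reached 0.161. Col3a1, Col1a1, Colec11, Dcn and Ecm1 had log2 values of -1.45, -1.25, -0.99, -1.01 and -0.25 and did not pass. No hepatocyte marker passed over all genes and 3 fell when adjusted over the list alone (camera adjusted p = 0.696); the median log2 value was -0.10 and the mean 0.03. That list was lower without untreated replicate 2 (adjusted p = 0.0181) and higher without 5-HT treated replicate 3 (adjusted p = 0.046). Alb had 554 ± 109 FPKM in untreated and 896 ± 464 FPKM in treated libraries, and Trf had a log2 value of -0.23. Ighm, a B cell and plasma cell marker, had 184 ± 17.6 and 655 ± 480 FPKM and Jchain 56.2 ± 28.3 and 148 ± 97.7 FPKM, neither past the threshold (edgeR adjusted p = 0.068 and 0.156). No member of that list passed over all genes and 2 rose when adjusted over the list alone (camera adjusted p = 0.757, higher, with a median of -0.22 and a mean of 0.27). No T cell or NK cell marker passed (camera adjusted p = 0.257 and 0.696); Trac, Trbc2, Gzma and Gzmb had log2 values of 0.81, 0.38, -1.55 and -0.39. The T cell list was higher without 5-HT treated replicate 3 (adjusted p = 0.00488) and the NK cell list lower without untreated replicate 2 (adjusted p = 0.00591). Mitochondrial genes took 5.72% of counts in 5-HT treated replicate 2, against 2.2% to 3.33% in the other 5 libraries. 
Markers of the remaining cell types did not pass as lists. Camera adjusted p was 0.432 for monocytes, 0.696 for conventional dendritic cells, 0.202 for plasmacytoid dendritic cells, 0.696 for platelets, 0.326 for mast cells and basophils, and 0.0891 for sex-linked genes. The monocyte list was higher without untreated replicate 2 (0.00108), the plasmacytoid list lower without 5-HT treated replicate 2 and with the replicate block (0.0129 and 0.00616), and the sex-linked list lower in 5 of 23 alternative settings, among them the fits without untreated replicate 2 and without 5-HT treated replicate 1 (0.00083 and 0.0451). It was 0.808 for cholangiocytes (higher, with a median log2 value of -0.18 and a mean of 0.06) and 0.757 for erythroid cells (higher, median -0.51, mean 0.07). By edgeR, 1 erythroid gene, Slc4a1, rose (log2 3.37, at a mean of 0.203 FPKM in treated libraries) and 1 sex-linked gene, Xist, fell, both chosen after their values were seen. Adjusted over the list alone these passed again, 1 platelet gene rose and 1 fell, and 1 mast cell gene fell. Their most abundant markers had log2 values of -0.28 (Plac8) and 0.39 (Ms4a4c), -0.07 (Clec9a) and 0.01 (Zbtb46), -0.28 (Ly6d), -2.08 (Pf4) and -0.11 (Itga2b), -0.49 (Kit) and -0.25 (Gata2), -0.21 (Ddx3y) and -0.20 (Eif2s3y), -0.37 (Krt18) and -0.44 (Krt8), and -0.59 (Hbb-bs) and -0.43 (Hba-a1), none past the threshold, and Siglech had 15.8 ± 8.14 and 7.84 ± 6.54 FPKM. The value of Zbtb46 was negative in every limma fit on FPKM, whatever the scaling.

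Of the other program lists, cholesterol synthesis (3 of 20 genes, Idi1, Stard4 and Hmgcs1, fell; camera adjusted p = 0.0832), p53 targets (3 of 14, Gdf15, Sesn1 and Trp53inp1, fell; camera adjusted p = 0.126, and 0.0169 with fry) and mitochondrially encoded genes (none of 13 passed, all 13 with positive log2 values, camera adjusted p = 0.117) did not pass. Cholesterol synthesis passed as lower in 12 of 25 alternative settings. Its adjusted p was 0.02 without 5-HT treated replicate 2 and 0.038 without untreated replicate 1. Mitochondrially encoded genes passed as higher without a filter on counts and without 5-HT treated replicate 3 (0.0175 and 3.86e-05), and MHC class II in 5 of 25 settings, with adjusted p down to 0.0119. Not past the threshold either were MHC class II (0.122), MHC class I (0.696), heat shock (0.302), immediate early genes (0.677), cAMP and CREB targets (0.696), endosome sorting (0.696), autophagy (0.735) and cell cycle genes (0.735), each value a camera adjusted p. In these, Hspb1 rose among heat shock genes, Crem and Pde3b rose and Per1 and Nr4a3 fell among cAMP targets, Snx2 fell among endosome genes, and Tfe3 rose and Wipi1 fell among autophagy genes; the genes named in this paragraph were chosen after their values were seen. Adjusted over the list alone, 3 cholesterol synthesis genes and 3 p53 targets fell, 1 heat shock gene rose, 3 cAMP targets rose and 3 fell, 1 autophagy gene rose and 2 fell, and none of the others named here passed. The 32 lists that did not pass had camera adjusted p from 0.0561 to 0.942.

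Of 3610 annotated terms, 89 were higher and 52 lower by camera, and none with an estimated correlation; other divisions of the libraries into groups of 3 called between 33 and 229 terms. The term of phagocytosis recognition was among the highest (82 genes, 19 rose, camera adjusted p = 3.17e-14), but 65 of its genes are immunoglobulin segments. Without these, 3 of its 17 genes rose and the camera adjusted p was 0.0406. For phagocytosis engulfment, 24 of 99 genes rose and 1 fell (camera adjusted p = 5.64e-14), 65 being immunoglobulin segments; without them 8 of 34 rose and 1 fell (camera adjusted p = 0.00233). Phagocytic vesicle, a term without immunoglobulin segments, was higher (10 of 76 rose and 3 fell, camera adjusted p = 0.0136), and positive regulation of phagocytosis was higher with its segments but not without them (camera adjusted p = 0.0114 and 0.0572). The terms of phagocytosis (0.16), phagosome (0.0572) and Fc gamma receptor-mediated phagocytosis (0.2015) did not pass. With an estimated correlation, the camera adjusted p of each of these terms was 1 in the full test and 0.998 in the test without segments. Of 147 tested immunoglobulin segments, 30 rose and none fell. The endocytosis term of 158 genes did not pass (7 rose and 6 fell, camera adjusted p = 0.624). Among terms without immunoglobulin segments, leukocyte cell-cell adhesion (8 of 21 genes rose, camera adjusted p = 2.39e-10) and the endoplasmic reticulum chaperone complex (6 of 13 rose, camera adjusted p = 9.3e-07) were higher. Without untreated replicate 2, 112 terms were lower, and without 5-HT treated replicate 3, 138 were higher.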

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

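Of the 70 named genes past the threshold, 30 kept their direction and call in every alternative fit that tested them. Over 1573 fits of these genes, 1365 kept the call, 208 lost it and 0 changed direction. Every called gene had groups that did not overlap, so a change of direction was unlikely from the start. Over 325 fits of the 13 lists past the threshold, 296 kept the call, 29 lost it and 0 changed direction. None of the 13 kept it in every setting, as all lost it with an estimated correlation. Most of these settings used camera with the preset correlation, with which other divisions of the libraries also called 12 to 19 lists. No scaling moved the median log2 value of all genes by more than 0.1. Of 31731 genes with a count, 16641 had counts high enough to be tested. On simulated counts with 200 genes changed, edgeR found 2 of 67 genes changed 1.5-fold and 51 of 66 changed 4-fold. The real comparison called 1288 genes, so these shares need not hold for it. Fits on counts recovered from FPKM were not run because counts were deposited. The causes of the differences that follow were not tested, except that leaving out a library leaves fewer samples.

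The number of genes higher and lower was 1241 and 1018 with DESeq2, 353 and 219 with limma without a filter, 360 and 308 with limma on TPM, and 1179 and 1123 with array weights. Without 1 library in turn it ran from 218 to 672 higher and from 111 to 675 lower; of the 70 named genes, 35 lost the call without untreated replicate 1, 38 without untreated replicate 3 and 21 without 5-HT treated replicate 1. Lists lower numbered 8 without a filter on counts, and 5 with a mean FPKM of at least 0.5, with limma on log2(FPKM + 1), with a pseudocount of 5, with limma without a filter, with quantile normalization, with median-of-ratios scaling of FPKM, without trend, with array weights and with the replicate block. Without 1 library they ran from 3 to 6 lower and from 10 to 13 higher, and terms from 70 to 138 higher and from 35 to 112 lower. With an estimated correlation 0 lists were higher and 0 lower, and 0 terms higher and 0 lower; fry called 7 lists higher and 2 lower. Equal replicate numbers are not said to mark pairs, and deviations of same-numbered libraries correlated at 0.0749, 0.0727 and -0.0115 over genes; with a replicate block 542 genes were higher and 354 lower, and 9 of the 70 named genes lost the call (Hsd3b5, Clec4n, Marco, Epn2, Hip1, Dab2, Ddc, Htr7 and S100a9). Without immunoglobulin segments, 83 terms were higher and 50 lower.

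All results that changed direction were ones not past the threshold as reported. The erythroid list was lower, with a camera adjusted p of 0.604 (mean FPKM of at least 0.5), 0.646 (mean FPKM of at least 5), 0.938 (DESeq2), 0.599 (limma, with and without trend), 0.646 and 0.532 (pseudocounts of 0.1 and 5), 0.619 (limma, mean FPKM of at least 5), 0.57 (quantile), 0.588 (median-of-ratios scaling of FPKM), 0.676 (TPM) and 0.163 (array weights). With a mean FPKM of at least 5 the adjusted p was 0.959 for alternative activation, 0.825 for cell cycle and 0.665 for cholangiocytes, and with limma at that minimum 0.619 for cell cycle and 0.632 for cholangiocytes. It was 0.961 (pseudocount of 0.1) and 0.956 (TPM) for NK cells, 0.97 (limma without a filter) for serotonin genes and 0.874 (array weights) for B and plasma cells. The log2 value of Zbtb46 was -0.0176 with limma (also without a filter, at a mean FPKM of at least 5 and without trend), -0.0192 and -0.0125 with pseudocounts of 0.1 and 5, -0.042 with quantile normalization, -0.0134 with median-of-ratios scaling of FPKM, -0.0603 on TPM, -0.0758 with array weights and -0.0129 with the replicate block; that of Clec9a was 0.0293 with array weights. Without 1 library in turn, log2 values ran from -0.164 to 0.0429 for Clec9a, -1.57 to 0.0486 for Hba-a1, -0.187 to 0.012 for Itga2b, -0.78 to 0.348 for Krt18, -0.922 to 0.146 for Krt8, -1.07 to 0.137 for Ly6d, -0.455 to 0.0456 for Plac8, -0.0158 to 0.632 for Trbc2 and -0.206 to 0.163 for Zbtb46. Adjusted p of lists that changed direction there ran from 0.051 to 0.979 for B and plasma cells, 0.247 to 0.985 for MHC class I, 0.00591 to 0.986 for NK cells, 0.00488 to 0.941 for T cells, 0.481 to 0.979 for apoptotic cell uptake, 0.374 to 0.985 for cell cycle, 0.178 to 0.933 for cholangiocytes, 0.401 to 0.984 for endosome sorting, 0.264 to 0.614 for erythroid cells, 0.138 to 0.939 for heat shock, 0.0181 to 0.979 for hepatocytes, 0.108 to 0.725 for immediate early genes and 0.304 to 0.944 for serotonin genes.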

Other observations

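The genes in this paragraph were chosen after their values were seen, and were not tested as groups. The 5 genes that follow rose, while the fixed endothelial list, which holds none of them, had 1 gene that rose and 5 that fell (median log2 -0.36, camera adjusted p = 0.0733). Ednrb, the endothelin receptor B gene, went from 27.3 ± 7.47 to 168 ± 34.7 FPKM (SD, n = 3 each; log2 2.63, edgeR adjusted p = 0.00164), Angpt2, the angiopoietin-2 gene, from 5.08 ± 0.694 to 25.2 ± 4.17 FPKM (log2 2.32), Inhbb, an activin subunit gene, from 15.97 ± 1.31 to 81.1 ± 4.27 FPKM (log2 2.35), Kcnj8, a potassium channel gene, from 2.06 ± 0.169 to 16.7 ± 2.86 FPKM (log2 3.01), and Sele, the E-selectin gene, from 2.47 ± 0.246 to 9.77 ± 1.99 FPKM (log2 1.99). Outside the fixed lists, Ch25h, which encodes a cholesterol hydroxylase, rose 12.4-fold, Acod1, which makes itaconate, 4.59-fold, the co-stimulatory receptor gene Tnfrsf9 13.4-fold and the formyl peptide receptor gene Fpr2 5.54-fold (edgeR adjusted p = 0.00235, 0.00107, 0.00051 and 0.00107). In the alternative activation list, which did not pass (3 of 16 rose and 3 fell, and 4 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.498), the chemokine genes Ccl17, Ccl22 and Ccl24 fell by 2.52, 1.88 and 1.21 on the log2 scale, while Tgfb1, Il4ra and Cd163 rose by 0.76, 0.75 and 0.84.

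For fatty acid beta-oxidation, 11 of 46 genes fell and none rose (median log2 -0.42, camera adjusted p = 1.36e-06), and for the degradation of valine, leucine and isoleucine 17 of 51 fell and none rose (median log2 -0.41, camera adjusted p = 3.71e-09); both had an adjusted p of 1 with an estimated correlation. Other lower terms included tryptophan metabolism (10 of 38 fell) and drug metabolism by cytochrome P450 (7 of 58 fell), with no gene higher in either. Hepatocyte RNA was present, with Alb at 554 and 896 FPKM in untreated and treated libraries. No hepatocyte marker passed over all genes (median log2 -0.10), while 3 fell and none rose when adjusted over the list alone. Which cells these falls came from was not tested. Among single genes chosen after their values were seen, Cry1 rose 2.63-fold and Per1 was 2.03-fold lower (edgeR adjusted p = 0.00157 and 0.0121), and Dbp, Nr1d1 and Arntl did not pass (log2 -0.13, -0.19 and -0.49). Xist was at 1.09, 0.3 and 1.15 FPKM in untreated replicates 1 to 3 and at 0.01 in each treated library, while the Y-linked genes Ddx3y and Eif2s3y were expressed in both groups at 31.2 and 26.9 FPKM and at 22.5 and 19.6 FPKM. Whether the groups differ in the sex of their animals was not tested. Such a difference could not be told apart from the treatment.

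All tests in the paragraphs that follow were chosen after the results they bear on were seen. Of the 10 ways to divide the 6 libraries into groups of 3, the real one called 1288 genes by edgeR and the highest other 0 (1430 at an unadjusted p under 0.05; by DESeq2 the highest other was 181 against 2259), so 1 division gave as many. For lists, 9 divisions gave as many as the real 13, with a highest other value of 19, and for terms 6 gave as many as the real 141, with a highest other value of 229. Divisions this few cannot give a share under 0.05. Each other division sets 2 libraries of one group beside 1 of the other, so part of the treatment difference stays in it.

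The Kupffer cell list was higher while the endothelial markers moved apart. A larger share of Kupffer cells, or a smaller share of endothelial cells, with no change of single genes would give the markers of each type 1 common fold. Of 17 Kupffer cell genes, 7 lay farther than 2 SE from their weighted mean (log2 0.54), where chance gives about 1.41, and the values ran from -0.16 to 1.58. Of 13 endothelial genes, 7 lay that far from theirs (log2 -0.15; chance gives about 1.08), with values from -1.71 to 1.79. If each marker came from its own cell type alone, a shift in cell shares would leave part of both patterns unaccounted for. Whether other cells in the preparations also express these markers was not checked. Markers shared between cell types would have unequal folds under such a shift, so the test does not decide. A shift together with changes of single genes, and an effect of 5-HT on either cell type, also stay open and were not tested.

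In the same libraries 7 NF-kB and 6 neutrophil genes rose, and neutrophil RNA is a candidate source of the inflammatory rise. If it carried the rise, the excess over the untreated mean in each treated library would follow that of the neutrophil genes. Over the 3 treated libraries, the log2 excess of the 6 called neutrophil genes had slopes of 0.85 to 1.13 on their mean, and that of the 7 called NF-kB genes a median slope of -0.29, from -0.62 to 0.31. The neutrophil slopes were taken on the mean of the same genes, which fixes their average, so they are no independent benchmark. The median NF-kB slope rests on 5-HT treated replicate 2, without which it was 0.63. Neutrophil RNA as a source of part or all of the rise therefore stays open. Exposure of the treated samples to a bacterial product might also raise these genes; the type I interferon list, which endotoxin raises, had a median log2 value of -0.40 and passed as lower in 6 of 25 alternative settings, but the time since such an exposure is not known, so exposure and 5-HT itself cannot be told apart.

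The terms of phagocytosis recognition and engulfment were higher together with the immunoglobulin segments annotated to them. Without the segments the camera adjusted p was 0.00233 for engulfment and 0.0406 for recognition, but 0.998 for both with an estimated correlation, and other divisions of the libraries called 33 to 229 terms. Whether the segments carry the whole rise of either term therefore cannot be told, although 8 of 34 other engulfment genes rose by edgeR. The median log2 values were 0.44 and 0.38 without the segments, against 1.14 and 1.59 with them. Plasma cells or B cells in the treated preparations are a candidate source of the segments' reads; this was not tested beyond the marker list, and an effect of 5-HT on the remaining genes stays open.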
